A study of Drosophila melanogaster with 18 samples.

How the data were processed

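The RNA-seq measured transcripts of Drosophila ovarian somatic cells (OSCs), a cultured line from the follicle cell lineage of the fly ovary, 2 days after RNA interference against EGFP (the control), piwi, mael or brm. The ChIP-seq measured DNA bound by Brm, Polybromo and Osa, subunits of the SWI/SNF chromatin remodelling complexes, in control and Piwi knockdown OSCs, each with an input library. Brm and Polybromo shared 1 input per condition and Osa had its own. Of the 18 samples listed, 14 OSC libraries were analysed: 4 of RNA and 10 of ChIP or input. The 4 ovary libraries were not analysed here. Each group held 1 library, so no difference has a replicate check, and no p-value or standard error is given.

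The deposited RPKM values, reads scaled by the authors to feature length and library size, cover 35502 features, 35329 of them transcripts with RefSeq accessions and 173 of them transposons with FlyBase identifiers. Per the submitters' processing notes, Bowtie2 2.2.4 and the dm6 build were used. The rule by which the authors counted reads, and how reads that match several copies were assigned, are not given in the sources used here. In the RNA table, 4 columns of values matched no sample and were not used in any step.

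Each library's total was found from genes with 1 transcript, as the number that turns RPKM times annotated length into whole reads. For each feature, the shortest length between 20 and 80000 bases that made its values whole was then taken. Over 99% of values above 0 came within 0.01 of a whole read. This share follows largely from how the lengths were chosen, and too short a length would understate a feature's reads. The RNA libraries held 8983374 reads (EGFP), 8965485 (Piwi), 9498401 (Mael) and 4865534 (Brm). The listed features held 99.9% of the EGFP library's reads. ChIP and input totals ran from 475226 reads (input of Osa, Piwi knockdown) to 2779826 (control Brm ChIP), and the listed features held 29.7% to 38.7% of them. Most RNA features had even numbers of reads (62.8% in the EGFP library), so both mates of a pair appear to be counted, and intervals for RNA use 1 fragment per 2 reads.

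Transcript accessions were matched to gene symbols with the RefSeq table of the Release 6 assembly: 34925 transcript identifiers matched and 404 did not. RPKM of a gene's transcripts were summed, a choice made after the layout of the tables was seen. Reads shared by isoforms may enter such a sum more than once. Transposon names of other species (47) stayed out of the comparisons, which left 16956 features. Coordinates are those of the gene in Release 6, 1-based. Transposon values belong to a family, with no single position.

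RNA was compared with the EGFP library as log2(RPKM + 1). A feature was tested when its mean over both libraries was at least 5, and was called higher or lower at a 2-fold difference on that scale, which understates changes of weakly expressed features. Intervals are 95% Clopper-Pearson intervals of the ratio of fragments without a pseudocount. They cover counting error only, as do floors of 3 counts. The lists of genes and transposons (29) were fixed before the data were examined. A list with at least 5 tested members was set against 10000 random lists matched on mean expression in 20 bins, and called outside when its median lay beyond the central 95%. Genes named in the text are the targeted genes, the 10 highest and 10 lowest calls, up to 4 members of each list outside its range, and up to 8 per transposon list. Members of overlaps are named besides. ChIP features are the 5 with the largest and the 5 with the smallest change, the transposons named from RNA and the targeted genes. Features named for enrichment, or with at least 50 reads, were added after the values were seen, as were the transcripts of single genes. Any other named gene is said to be chosen after its values were seen. The elements 297, 412, 17.6 and 1731 are written with the prefix Dm in the text and without it in the plots.

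ChIP enrichment was log2 of ChIP over its own input, with the 5th percentile of the input's values above 0 added to both. Features were kept when the mean of the inputs used was at least the median of all features. The change on Piwi knockdown was the enrichment in the knockdown minus that in the control, relative to the median of the kept features. Sets were compared with 10000 random sets matched on control enrichment, or on input for enrichment itself. ChIP intervals are normal intervals of log read ratios at 95%.

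The steps were tested on simulated reads. With 50 genes per fold size, the rule of size found 38% of 2-fold and 98% of 3-fold changes in the Piwi comparison, 32% and 92% in the Mael comparison, and 46% and 86% in the Brm comparison. It called 10, 7 and 16 unchanged features, respectively. In ChIP, 183 (Brm), 186 (Polybromo) and 185 (Osa) of 200 moved features passed a 2-fold change, but so did 961 of 8320, 1288 of 8314 and 1136 of 8293 unmoved features. A 2-fold ChIP change of a single feature is therefore not a call by itself. Overlaps between knockdowns were set against 100 simulations of unchanged libraries around the shared control. These drew counting error only, and no other variation of a library.

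Alternatives covered the pseudocount, the floor, the fold, the scaling and the input. Transcripts taken singly, libraries thinned to equal depth, totals without transposon reads or without the 100 most abundant features, and read minimums were added after the data were seen. For ChIP sets, the value compared across alternatives is the set's median minus that of its random sets, with a change of sign counted as a reversal. That definition was set after a first version of those results had been seen. The test of input on the genes that rose was also rebuilt after its first result, and both results are given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.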

Results

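RNA of OSCs was profiled 2 days after knockdown of EGFP (control), Piwi, Mael or Brm, with 1 library each. Piwi is the nuclear Argonaute protein that silences transposons with piRNAs, Maelstrom (Mael) is a factor needed for that silencing, and Brahma (Brm) is the ATPase of the SWI/SNF complexes. The series concerns transposons that Piwi silences by way of Mael and whose expression depends on Brm. ChIP-seq of Brm, Polybromo and Osa compared the chromatin binding of these subunits with and without Piwi. Elements that FlyBase names by a number alone carry the prefix Dm here. The RNA libraries held 8983374 (EGFP), 8965485 (Piwi), 9498401 (Mael) and 4865534 (Brm) reads, and the ChIP and input libraries between 475226 and 2779826. There were no replicates, so all differences are between single libraries.

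Each targeted gene was lowest in its own knockdown. piwi (chromosome 2L, 10982205 to 10987420) had 81.5 RPKM in the control, 10.95 in the Piwi knockdown, 57.7 in the Mael knockdown and 21.3 in the Brm knockdown. Its log2 ratio in its own knockdown was -2.79 (interval -3.16 to -2.65). mael (3L, 22721203 to 22726234) had 14.5 RPKM in the control and 13.3, 4.20 and 15.8 in the Piwi, Mael and Brm knockdowns, a log2 ratio of -1.58 in its own. brm (3L, 15970082 to 15982869) had 6.66 RPKM in the control and 6.19, 7.40 and 0.54 in the same order, from 321 reads in the control and 14 in its own knockdown. Its log2 ratio was -2.31, with a mean of both libraries under the floor of 5 RPKM. The Brm knockdown thus also held less piwi RNA, with a log2 ratio of -1.55 relative to the median feature of that comparison.

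Loss of Piwi raised LTR retrotransposons of the gypsy superfamily, elements related to retroviruses that are active in follicle cells. mdg1 rose from 16.0 to 513 RPKM (log2 4.92, interval 4.88 to 5.13) and Quasimodo from 40.5 to 918 RPKM (log2 4.47, interval 4.42 to 4.58). Tabor rose by 3.24 on the log2 scale, Dm297 by 2.28, Dm412 by 2.19 and blood by 2.05, and gypsy went from 330 to 1172 RPKM (log2 1.82, interval 1.80 to 1.86). Stalker2 rose by 1.72 and Dm17.6 by 1.26. Of 33 transposons tested, 11 rose and 0 fell. Of 14 elements listed beforehand as sensitive to Piwi in ovarian somatic cells, 9 reached the floor. All 9 rose, with a median of 2.19, above all random lists (percentile 100). The floor uses the mean of both libraries, so an element low in the control enters more readily if it rises. With a floor of 1 RPKM the list's median was 1.94 (percentile 100).

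Other transposon classes showed smaller differences. Of 19 gypsy-superfamily elements tested, 10 rose, with a median of 1.26 (0.39 with elements of at least 1 RPKM). The DNA transposon mariner2 rose by 1.14, while pogo was at 0.66, FB at 0.60 and hopper at -0.34. No LINE element passed the rule, and Juan had the largest ratio among them (0.47). Among the other LTR elements, roo was at 0.72, diver at -0.60, 3S18 at -0.37, Dm1731 at -0.20 and copia, the most abundant element, at -0.26 (15484 RPKM in the control). The medians of the LINE list (0.10) and of the copia and BEL list (-0.26) lay inside their random ranges.

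Among genes, 52 rose and 25 fell of 5357 features tested. The highest were Abl, a tyrosine kinase (log2 2.64, interval 2.62 to 2.68), Snoo, a Smad cofactor (2.58), udd, a factor of ribosomal RNA transcription (2.49), luna, a Krüppel-like factor (2.31), and Fas2, a cell adhesion molecule (2.07). In Snoo, 1 of 4 transcripts held the rise (36.4 to 225 RPKM), while the others together stayed at 0.53 and 0.81 RPKM. In luna, 1 of 3 transcripts did (16.1 to 85.0 RPKM). The leading transcripts of Abl and udd had 74.2 and 60.5 RPKM in the control input, where the median over tested genes was 3.30. The genes that fell furthest besides piwi were CG2065 (-1.52), wrapper, a glial surface protein (-1.51), the transcription cofactor nab (-1.38), the glutamate receptor subunit GluRIIB (-1.31), CG6656 (-1.31), CG34443 (-1.29), Kal1 (-1.25) and the muscle actin Act57B (-1.22, interval -1.35 to -1.11). snoRNA:Psi28S-1175a also passed the rule, with 11 reads in the control and 3 in the knockdown.

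Several pathway lists lay outside their random ranges with no member past 2-fold. The EGF receptor list was above (median 0.32 over 8 genes, percentile 99.2), with the MAP kinase rl at 0.55 and the feedback inhibitor sty at 0.52, besides Mkp3 at 0.54 and aop at 0.34. The JAK/STAT list was above (median 0.31 over 6 genes), with Socs44A at 0.65 and Stat92E at 0.64. The Notch list was above (median 0.51 over 5 genes), with E(spl)m3-HLH at 0.61 and N at 0.51. Ecdysone response genes (0.28), germline markers (0.32, with pgc at 0.66 and squ at 0.64) and ovarian somatic markers (0.27, with tj at 0.50) were above as well. Immune genes were below (median -0.44 over 5 genes, with dl at -0.65 and cact at -0.50), and so were housekeeping genes (-0.19, with Gapdh2 at -0.35). With genes of at least 1 RPKM, the EGF receptor list (0.09) and the germline list (0.01) came inside their ranges.

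In the Mael knockdown the median feature lay at -0.12 on the log2 scale, and changes are given relative to it. mdg1 (4.69, interval 4.65 to 4.90), Quasimodo (3.20), Tabor (2.41) and Dm297 (1.80) were again the transposons with the largest rise. They passed the rule on the values as given, 4 of 33 transposons with 0 lower. blood (1.10), gypsy (0.99), Stalker2 (0.90), mdg3 (0.86) and Dm17.6 (0.59) did not pass it on those values. The list of Piwi-sensitive elements lay above its random range (relative median 1.45 over 8 elements), as did the gypsy superfamily (0.59 over 19 elements). The latter's median on the values as given went from 0.47 to 0.24 with elements of at least 1 RPKM. mariner2 was at 0.99, FB at -0.41, Juan at 0.30, Doc at -0.27, 3S18 at -0.24 and copia at -0.22.

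Of 5292 features tested in the Mael knockdown, 21 were higher and 22 lower on the values as given, and 37 and 16 once the median was set to 0, so the share of higher calls moved from 48.8% to 69.8%. The genes that rose most were lncRNA:CR44447 (2.07, from 8 and 49 reads), the cuticle protein gene Cpr57A (1.59), CG10581 (1.51), the GTPase Rac2 (1.45), the mitochondrial carnitine transferase CPT2 (1.41) and the ornithine aminotransferase Oat (1.34). The lowest besides mael were snRNA:U5:63BC (17 and 2 reads), BaraB (-1.33), CG44476 (-1.32), CG31922 (-1.24), OS9 (-1.21) and 4 non-coding RNAs with at most 19 reads in the control. Ribosomal protein genes lay above their random range (relative median 0.24 over 38 genes, 0 past the rule), with RpL4 at 0.90 and RpS14a at 0.66. The somatic piRNA pathway lay below (relative median -0.19 over 18 genes), with vret at -0.50, nxf2 at -0.43 and daed at -0.38. In that list, mael was the 1 member that fell past the rule.

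In the Brm knockdown the median feature lay at -0.34, and changes are given relative to it. Several of the transposons that rose without Piwi fell without Brm: blood (-2.21, interval -2.35 to -2.14), gypsy (-1.87, interval -1.97 to -1.80), Stalker2 (-1.60), mdg1 (-1.21) and Dm17.6 (from 13.5 to 4.75 RPKM). Dm297 (-0.93), springer (-0.87) and Transpac (-0.79) passed the rule on the values as given but not relative to the median. Quasimodo did not fall (0.48), and copia rose from 15484 to 35243 RPKM (1.52). Of 29 transposons tested, 10 fell and 1 rose on the values as given, and 5 fell and 2 rose relative to the median. The Piwi-sensitive list lay below its random range (relative median -1.21 over 7 elements), as did the gypsy superfamily (-0.79 over 15 elements). The latter's median as given went from -1.13 to -0.70 with elements of at least 1 RPKM. Doc3-element was at -0.67, Doc2-element at 0.60, FB at 1.04, mariner2 at 0.75, 3S18 at -0.98, diver at -0.62 and roo at 0.63.

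**Figure D1:**
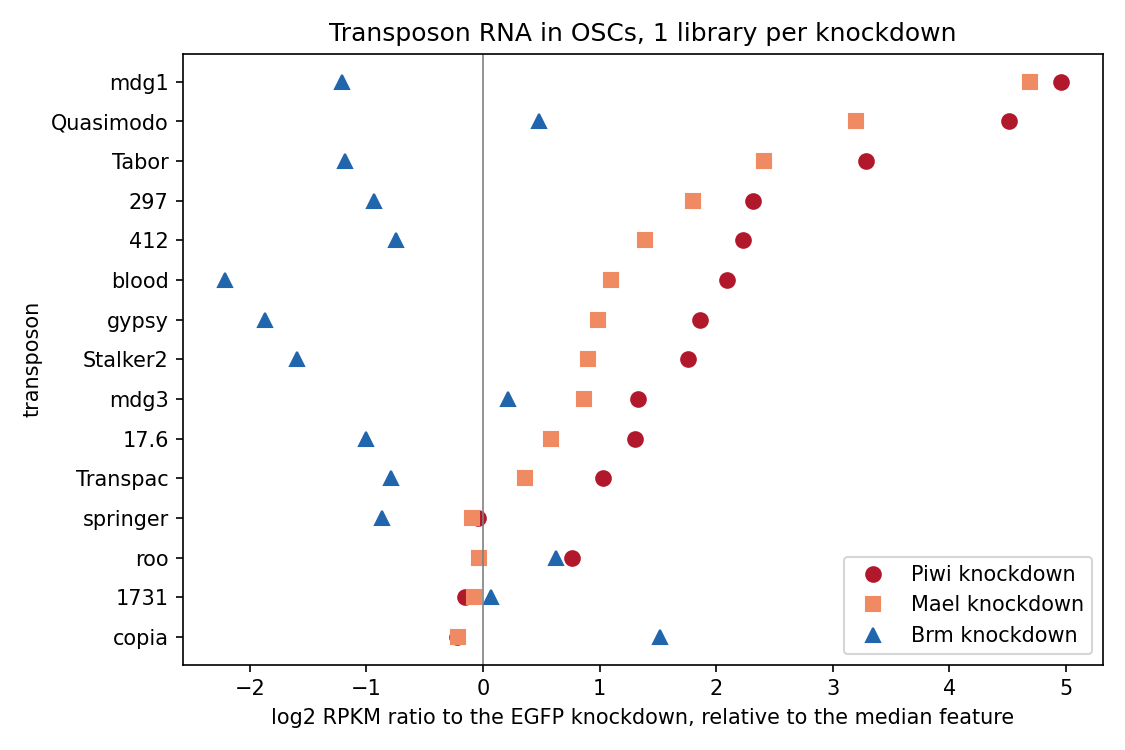
Transposon RNA in each knockdown as the log2 RPKM ratio to the EGFP knockdown, relative to the median feature, for 15 elements chosen after their values were seen, with 1 point per library. mdg1 sits at 4.96 without Piwi, 4.69 without Mael and -1.21 without Brm, while copia sits at 1.52 without Brm; Tabor and Dm412 lay under the 5 RPKM floor in the Brm comparison.

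Genes of DNA replication and the cell cycle were lower without Brm. Of 26 list members tested, 17 fell on the values as given and 11 relative to the median, and the list lay below its random range (relative median -0.93). Examples are RnrS, the small subunit of ribonucleotide reductase (-1.54), the helicase subunit dpa (-1.44), the licensing factor dup (-1.38) and Mcm3 (-1.35). Subunits of the SWI/SNF complexes were lower as a list (relative median -0.90 over 11 genes). Of these, 7 fell on the values as given and 1, Bap111 (-1.21), relative to the median, with polybromo at -0.99, Bap55 at -0.98 and mor at -0.98. Ecdysone response genes lay below (relative median -0.70 over 6 genes), where Ldh (-0.95), ImpL2 (-0.90) and br (-0.82) passed the rule on the values as given and 0 did relative to the median. That list's median came inside its range with genes of at least 1 RPKM.

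Heat shock and stress genes lay above their random range without Brm (relative median 0.64 over 16 genes). The chaperone genes Hsp70Ab (1.91) and Hsp70Aa (1.73), near-identical copies whose reads may be split, rose, GstD1 was at 1.06 and DnaJ-1 at -0.65. Ribosomal protein genes lay above as well (relative median 0.38 over 38 genes, 0 past the rule), with RpL18 at 0.72 and RpL5 at -0.23.

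The largest rise without Brm was that of PGRP-SA, a peptidoglycan receptor of innate immunity (0.74 to 65.2 RPKM, 5.58), followed by CG34445 (3.86), CG30269 (3.49), lncRNA:CR43918 (1 and 14 reads), CG12853 (2 and 18 reads), the growth-blocking peptide gene Gbp1 (3.12), CG12880 (3.11), CG14984 (3.09), the histone gene His2A:CG33844 (3 and 23 reads) and SmydA-1 (2.95). The genes that fell most were atilla (-4.21, 231 and 2 reads), CG34330 (-4.06, from 924 to 43.1 RPKM), wrapper (-3.92), nab (-3.27), Fkbp14 (-3.04), lncRNA:CR45722 (-3.01) and CG11899 (-2.98). Cpr67Fb (67 reads in the control), snRNA:U1:95Cc (21) and CG34263 (24) had 0 reads in the knockdown, where 3 reads are the floor.

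Of 5083 features tested in the Brm knockdown, 101 were higher and 548 lower on the values as given. With the median set to 0, 196 were higher and 210 lower, so the share of higher calls moved from 15.6% to 48.3%. The Brm library held the fewest RNA reads, and copia alone took 18.1% of them, against 7.96% in the control.

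The 13 features higher without both Piwi and Mael included mdg1, Quasimodo, Tabor and Dm297, besides the genes Abl, Oat, Rnf11, Rac2 and CG10581. The control input of the leading transcripts was 22.5 (Abl) and 6.58 (Rnf11) times the median of tested genes. It was 2.32 for CG10581, 1.47 for Rac2 and 1.36 for Oat. Independent lists would share 0.174 features, and simulated unchanged libraries shared 1. The simulations drew counting error only, so their lists held a median of 2 and 1 features, against 53 and 17 here. Their overlap is therefore no measure of what lists of the observed size would share. The 3 features lower in both were Lcp9 and a pair of snoRNAs, against 0.101 for independent lists and 1 simulated (range 0 to 3), so these lay inside the simulated range. Across the 32 transposons tested in both comparisons, the log2 ratios had a Pearson correlation of 0.956 and a Spearman correlation of 0.863, with a covariance of 1.42 beside 0.00419 in the simulations. Across genes the Pearson correlation was 0.457, below the simulated 0.529, and the covariance 0.0491 beside 0.0175. The Piwi ratio to EGFP and the Mael ratio to Brm share no library. They had a Pearson correlation of 0.854 across 30 transposons (Spearman 0.649) and 0.0891 across genes. Without Brm, however, 8 of the 11 transposons that rose without Piwi lay under the median feature, counted without the floor. With Brm as the denominator, a positive correlation can thus arise without any effect of Mael. Features are not independent replicates, and part of the excess in the overlaps may come from the shared control.

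Between the Piwi and Brm knockdowns, 13 features were higher in the first and lower in the second on the values as given. They were the transposons mdg1, Dm297, blood, gypsy, Stalker2 and Dm17.6, besides Abl, Snoo, udd, luna, Oat, CG9837 and the unnamed transcript NR_125084. Over the median of tested genes, the control input of their leading transcripts was 22.5-fold (Abl), 18.4 (udd), 4.06 (Snoo) and 2.78 (NR_125084). It was 1.88 for luna, 1.86 for CG9837 and 1.36 for Oat. Transposon reads counted on some of these transcripts may thus add to the overlap. Independent lists would share 4.42. The simulations shared 0, but from lists with a median of 2 and 7 features, against 40 and 548 here. At 1.5-fold, 65 features were shared against 68.7 for independent lists, so the excess was absent there. That count also used the values as given, whose median without Brm was -0.34. At that fold, 1573 of 5083 features were lower without Brm. An overlap at 1.5-fold relative to the median is not given here. Relative to the median of the Brm comparison, Abl (-0.96), udd (-0.93), Dm297 (-0.93), luna (-0.79), Oat (-0.78) and Snoo (-0.71) stayed under 2-fold. The 14 features lower in both included piwi, wrapper, nab, GluRIIB, Kal1, Act57B and Buffy, against 2.43 for independent lists and 1 simulated. Higher in both were Fas2, lncRNA:CR43264 and snRNA:U4:39B (3, against 0.419 for independent lists and a simulated range of 0 to 3). Across 29 transposons the Pearson correlation was -0.36 and the Spearman correlation -0.29, with a covariance of -0.44 beside 0.00404 simulated. Across genes the Pearson correlation was 0.163, beside a simulated 0.445, and the covariance 0.0316 beside 0.0176. Of the 11 transposons that rose without Piwi, 8 lay under the median feature without Brm. The 11 include Tabor and Dm412, which were under the floor in the Brm comparison. Part of the overlaps in the same direction may come from the shared control, which pushes both ratios the same way and so does not account for the opposite features.

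In control OSCs, Brm ChIP over input was higher at ribosomal protein genes (median 0.99 over the median feature, 23 genes) than in random sets matched on input. EGF receptor genes (0.69), somatic piRNA pathway genes (0.57), heat shock genes (0.55), SWI/SNF subunits (0.37) and cell cycle genes (0.36) were above their ranges too. Transposons lay slightly lower than their random sets for Brm (-0.26 over 116 elements) and Polybromo (-0.06, inside the range over all features), although springer (1.09) and gypsy (0.64) stood above the median feature for Brm. Polybromo was highest at copies of the histone H4 gene, with His4:CG33873 at 4.34 and His4:CG33869 at 4.27, copies of similar sequence between which reads may be split, and at Quasimodo it stood at 1.48. Osa over its own input was higher at transposons (1.21 over 102 elements, random range -0.27 to 0.47), with Dm17.6 at 3.34, Stalker2 at 3.21 and Quasimodo at 3.04. Transposons took 10.0% of the control Osa ChIP reads, against 6.35% of its input and 10.1% of the control input of Brm and Polybromo. The Osa enrichment thus depends on an input with a smaller transposon share, and was not tested over the other input. The features with the largest Brm enrichment, chosen after their values were seen, were lncRNA:CR44204 (3.12), lncRNA:CR43644 (2.94), lncRNA:CR44619 (2.68), lncRNA:CR44276 (2.63) and lncRNA:CR43838 (2.59).

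On Piwi knockdown, the signal of Polybromo over input rose 3.22 on the log2 scale at Quasimodo (interval 3.13 to 3.31), from 4587 to 48849 reads, while the input had 2476 and 2208. It also rose at gypsy (1.10, interval 1.04 to 1.17) and was 0.51 at springer, 0.32 at Dm297, 0.30 at blood, 0.06 at mdg1 and -0.18 at Dm412. Brm was 0.76 at gypsy, 0.75 at Quasimodo, 0.51 at Dm297, 0.33 at blood and 0.30 at mdg1, with no transposon past 2-fold. Osa was 1.27 at Quasimodo (interval 1.09 to 1.45), 1.18 at Dm297 and 0.87 at Dm17.6, but -0.67 at blood and -0.78 at springer. Under the alternatives, Osa at Quasimodo ranged from 1.47 to 2.42, outside that interval, and at mdg1 it went from -0.06 to as much as 0.69.

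As a set, the 11 transposons that rose in RNA without Piwi had a median change of 0.30 for Brm (percentile 84.7) and 0.11 for Polybromo (percentile 67.4), both inside the ranges of sets matched on control enrichment. For Osa it was -0.06, above the range of -3.49 to -0.69. These values are relative to a median Osa change of 0.44 over all features. Control enrichment was used for the matching and is also subtracted in the change. Random sets matched to high control values can thus fall by counting error alone. The place of the 11 elements above the range therefore shows no gain of Osa by itself. The set's distance from the random median, 1.83, was 0.88 without the input, 0.79 with the other inputs and 0.65 with at least 50 reads (percentile 97.9). All transposons together had a median of 0.04 for Brm, just below its range (0.05 to 0.25) and inside it without the input, -0.16 for Polybromo, below (-0.08 to 0.15), and -0.52 for Osa, above (-1.14 to -0.57). Through the same matching, a place below or above these ranges does not by itself show a loss or gain. The Osa result depended on the features kept, as its distance from the random median turned from 0.32 to -0.0411 over all features and -0.0573 with at least 50 reads. Across 33 transposons, the ChIP change and the RNA change had a Spearman correlation of 0.55 for Brm, 0.34 for Polybromo and 0.38 for Osa. These were 0.51, 0.28 and 0.33 without Quasimodo. Over the inputs of the other antibody set, the medians of the 11 elements for Brm and Polybromo and the Brm values at Quasimodo, gypsy and mdg1 turned negative relative to their references. With those inputs, Polybromo stood at 2.12 at Quasimodo and 0.03 at gypsy. Without any input, Brm stood at 0.80 at Quasimodo, 0.78 at gypsy and 0.32 at mdg1, near the values over its own input. Polybromo without input stood at 3.27 at Quasimodo and 1.13 at gypsy. The turn thus came with the Osa inputs, which also enter each Osa value over its own input. Why these inputs differ was not tested.

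**Figure D2:**
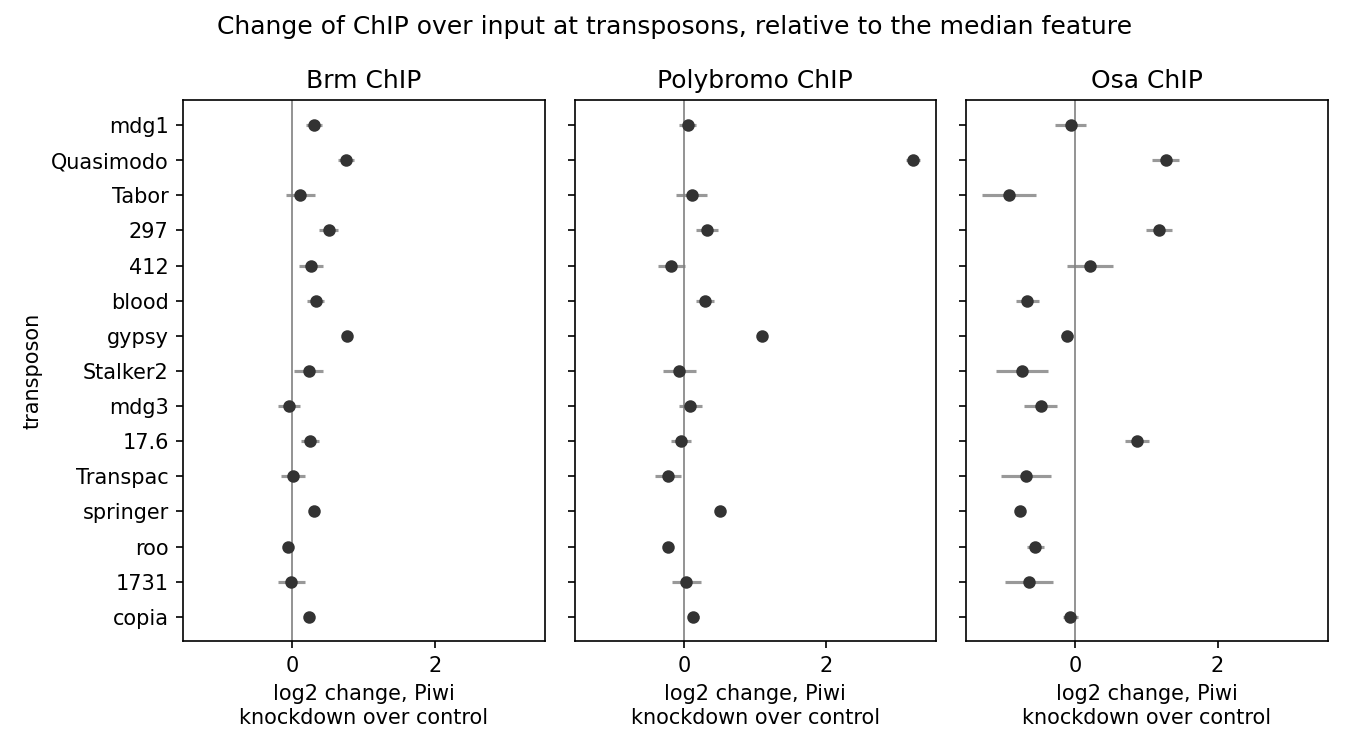
Change of ChIP over input on Piwi knockdown at 15 transposons chosen after their values were seen, on the log2 scale relative to the median feature, with 95% intervals for counting error only. Polybromo at Quasimodo stands at 3.22, and the other changes of the 3 antibodies lie between -0.93 and 1.27; with the other inputs, Brm turned negative at Quasimodo, gypsy and mdg1, Polybromo at mdg1 (-0.68), and Osa at gypsy and mdg1 (0.64) turned positive.

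Of the targeted genes, piwi had few reads of Brm ChIP (72 and 45), and the change there was 0.42 (interval -0.54 to 1.38). The changes at mael and brm are not given here. The features with the most extreme changes under the fixed rule had few reads. Examples are the non-coding genes snoRNA:Psi18S-1295 for Brm (-6.85, 5 and 0 ChIP reads) and mir-313 for Polybromo (-8.19, 1 and 0 reads), and the protein-coding gene CG4101 for Osa (9.41, 0 and 26 reads). With at least 50 reads on average, a minimum added after the data were seen, the largest Brm changes were at lncRNA:CR45668 (1.44), ITP (1.38) and croc (1.34), and the smallest at Ae2 (-1.03). For Polybromo, His3:CG33857 (1.81) and His3:CG33842 (1.42) followed Quasimodo. The change had a standard deviation of 2.22 across features for Osa, against 0.78 in simulated unmoved features, and of 0.78 against 0.69 for Brm and 0.87 against 0.82 for Polybromo. The spread of the Osa change thus exceeds that of counting error, by a cause that was not tested, and the Osa intervals understate the error.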

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

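The tests of explanations in this part were all chosen after the results they bear on had been seen, and no biological explanation was tested. Outside the comparisons, a transposon of another species, mini-me of D. pseudoobscura, had a signal above the control. Its RNA stood at 52.7 RPKM in the Piwi knockdown (2183 reads) and 15.6 RPKM in the control (646 reads). Its Osa ChIP, given without the input, stood at 1313 RPKM (7502 reads) against 214 RPKM (1540 reads). Also without the input, Brm ChIP stood at 130.5 RPKM in the Piwi knockdown and 88.8 RPKM in the control. Polybromo ChIP stood at 98.5 and 92.8 RPKM in the same order. No other element among the 47 of other species reached a 2-fold rise of RPKM + 1 with 100 reads. Without the added 1, ninja of D. simulans did so in the Mael knockdown (1.21 to 2.63 RPKM, 72 and 166 reads). RNA of mini-me stood at 29.9 RPKM (1311 reads) in the Mael knockdown and 3.65 RPKM (82 reads) in the Brm knockdown.

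In the Piwi knockdown, 6 genes rose more than 4-fold: Abl, Snoo, udd, luna, Fas2 and the unnamed transcript NR_125084. Counting error is argued against, since the lowest bound of their intervals was 1.71. A candidate explanation is that reads of transposon sequence were counted on transcripts that hold such sequence. The transcript that gained most reads in each gene had a median control input 3.42 times that of all tested genes (bootstrap interval 1.43 to 20.4), above the range of matched random genes (0.36 to 1.74). The test was rebuilt after its first form, which left out 1 of the 6 genes, gave 4.64. In the rebuilt form 4 of the 6 lay at 2 or more, and Fas2 (0.97) and luna (1.88) did not. For the 46 other risen genes the ratio was 1.23 (0.96 to 1.51), inside its range (0.74 to 1.33), but an earlier form of the test that left out 11 of them gave 1.55, above its range, so the explanation stays open there.

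In the Brm knockdown most genes lay lower on the values as given. A smaller library is argued against, since the median stayed at -0.34 with all libraries thinned to its reads. Transposon reads may take up part of the shift but not all of it, as the median was -0.21 without them in the totals. With the 100 most abundant features left out of the totals the median was 0.0219, over 7036 features instead of 5083. A larger share of reads on these 100 features (70.9% against 61.5% in the control) could account for the shift. Leaving them out lifts all other features by arithmetic, however. The value thus cannot tell a larger share on these features from a fall of the other genes. Of the 100, 44 lay above the control on the values as given, and 77 were ribosomal protein genes. copia alone went from 7.96% to 18.1% of reads, so on those values the rise was not general to abundant features. Relative to the median feature, however, the 38 listed ribosomal protein genes had a median of 0.38, above their random range. A fall of most RNA per cell stays open, since no value gives RNA per cell.

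Quasimodo had the largest Polybromo change among features with at least 50 reads. A change of the input is argued against, as the ChIP values alone gave 3.27. The other 10 transposons that rose in RNA had a median Polybromo change of 0.10 (bootstrap interval -0.04 to 0.32). RNA carried alike from all risen elements into the ChIP library is therefore argued against. Of the 11 risen transposons, 2 passed 2-fold for Polybromo, Quasimodo and gypsy (1.10). Carry-over in proportion to the amount of RNA was not tested as such. In the knockdown, copia took 6.64% of RNA reads, but 0.453% of the Polybromo ChIP and 0.512% of its input. gypsy had more RNA than Quasimodo there and a smaller change. A strict proportion was thus not seen at these elements, in single libraries. Carry-over particular to Quasimodo stays open. Quasimodo took 4.26% of the Polybromo library in the knockdown and 0.462% in the control. Amplification of few fragments could give such a share and cannot be told apart from binding, since the tables hold no positions within the element.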

How the results depend on the processing

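Alternatives chosen after the data were seen are thinned libraries, totals without transposon reads or without the 100 most abundant features, transcripts taken singly, and minimums of 20 reads (RNA) or 50 reads (ChIP). The planned ovary alternatives were not run, and no paired analysis was possible because each group holds 1 library. Counts depend on the threshold by construction, and for other shifts the cause was not tested. Counts are higher and lower calls. Piwi knockdown: 33 and 7 (pseudocount 5), 198 and 148 (no floor), 31 and 4 (mean of 20), 291 and 193 (1.5-fold), 17 and 1 (3-fold), 144 and 101 (100 features out), and 45 lower when thinned. Mael knockdown: 32 and 42 (pseudocount 0.1), 8 and 5 (pseudocount 5), 112 and 149 (no floor), 8 and 3 (mean of 20), 129 and 242 (1.5-fold), 5 and 2 (3-fold), 33 and 46 (thinned), 92 and 78 (100 features out), 37 higher (median set to 0), 34 lower (transposon reads out) and 14 lower (20 reads). Brm knockdown: 54 and 256 (pseudocount 5), 324 and 1080 (no floor), 31 and 191 (mean of 20), 196 and 210 (median set to 0), 245 and 1573 (1.5-fold), 39 and 119 (3-fold), and 479 higher (100 features out). brm in its own knockdown was -1.98 with the median set to 0 and -3.40 with a pseudocount of 0.1. Features in common at 1.5-fold numbered 52 higher and 54 lower for Piwi and Mael, and 65 opposite and 93 lower for Piwi and Brm, where independent lists would share 5.56, 8.75, 68.7 and 57.3. The excess of opposite features was thus lost on the values as given. At a mean of 20 they numbered 7, 0, 7 and 4, against 0.0839, 0.00503, 1.19 and 0.341, so that excess remained there.

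ChIP sets are given as the median minus that of random sets. With the inputs of the other antibody set, the 11 risen transposons went to -0.38 (Brm) and -0.68 (Polybromo), and the Brm change to -0.31 at Quasimodo, -0.28 at gypsy and -0.39 at mdg1. Polybromo at gypsy went from 1.10 to 0.03, at mdg1 from 0.06 to -0.68, and at Quasimodo from 3.22 to 2.12. Without the input, all transposons went to -0.0119 for Brm, inside the range. Over all features, control Polybromo at transposons went to -0.00438, inside. The Osa change at transposons reversed to -0.0411 over all features and -0.0573 with 50 reads. Osa at gypsy reversed to 0.99 (no input), 0.10 (all features), 0.33 (not relative to the median), 0.94 (other inputs) and 0.14 (50 reads). Osa at Quasimodo moved from 1.27 to 2.42 (no input), 1.47 (all features), 1.71 (not relative), 2.35 (other inputs) and 1.52 (50 reads). Osa at mdg1 moved from -0.06 to 0.69, 0.37, 0.64 and 0.19 with no input, not relative, with other inputs and with 50 reads. Counts of RNA calls were taken as moved when they changed by more than 1.5-fold.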

Other observations

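The tests in this part were chosen after the results were seen, except the lists and overlaps, which were fixed beforehand. Other gene lists lay outside their ranges on Piwi knockdown in Polybromo ChIP. These ranges were matched on control enrichment, which the change subtracts. For each antibody, a place outside them thus shows no gain or loss by itself. Ribosomal protein genes had a median change of 0.52 over 18 genes, above their random range (-0.47 to 0.23), and cell cycle genes 0.23 over 22 genes (random range -0.41 to 0.14). Heat shock genes lay at 0.16, just above (random range -0.67 to 0.15). Immune genes lay below for Brm (-0.40 over 16 genes, range -0.36 to 0.29). LINE elements (-0.19) and the gypsy superfamily (-0.16) lay below for Polybromo. For Osa, EGF receptor genes (0.10), Piwi-sensitive elements (-0.11), the gypsy superfamily (-0.47), housekeeping genes (0.36) and somatic piRNA pathway genes (0.18) lay above ranges that were themselves mostly negative.

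In control cells, Osa over its own input was enriched at Hippo pathway genes (1.11 over 11 genes), EGF receptor genes (1.19), housekeeping genes (1.09), ribosomal protein genes (0.54) and DNA transposons (1.33), all above their ranges. It was lower at chorion and vitelline membrane genes (-1.45 over 14 genes). The other input was not tried for these values.

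Genes of lists that lay inside their ranges, or had too few tested members for a range, also passed the rule without Brm. Relative to the median, the Bcl-2 family gene Buffy was at -2.34, the caspase Drice at -1.04, the Hedgehog receptor ptc at -1.11, Gapdh2 at -1.44 and Act57B at -1.57. The vitelline membrane gene Vm26Ab was at 2.72 and the chorion gene dec at -1.26. They were chosen after their values were seen. Markers of other cell types were mostly under the floor: 0 of 12 fat body genes were tested in any knockdown, and at most 1 of 13 hemocyte and 1 of 13 muscle genes.

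The remaining lists lay inside their ranges or had under 5 tested members. Relative medians for the Piwi, Mael and Brm knockdowns were -0.07, 0.00 and -0.31 for nuclear silencing and heterochromatin factors, 0.05, 0.17 and 0.14 for the Hippo pathway, -0.02, 0.08 and -0.25 for apoptosis and DNA damage, and -0.09, -0.11 and 0.01 for the small interfering RNA pathway. Polycomb targets and Hox genes had 1, 1 and 0 tested members, and the telomeric transposon list 0.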
